A study of Homo sapiens with 6 samples.

How the data were processed

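Total RNA of human umbilical vein endothelial cells (HUVECs, primary cells of the lining of the umbilical vein) was measured on 6 whole-transcript Affymetrix arrays, 3 from cells transfected with a scrambled siRNA and 3 from cells transfected with an siRNA against MAP4K4, a serine/threonine kinase. Per the labels' protocols, cells were grown in EGM-2 medium, transfected with a lipid reagent and moved to EBM-2 medium without serum overnight, and RNA was extracted with Trizol, converted to targets with the Ambion WT Expression Kit and labelled with biotin. The series description states that serum was withdrawn 24 hours after transfection, that cells were harvested 48 hours after the siRNA was added, and that cells were prepared on 3 occasions, which gave the 3 biological replicates of each group. Whether the occasions differed in cell lot or donor is not given in the sources used here. The siRNA sequences, the array model and the software versions are also not given in the sources used here.

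The deposited value table holds an intensity for each of 25927 probe sets on each array, on a linear scale. Per the submitters' processing notes, RMA and the affy package were used, with no version and no order of steps. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a probe set, so that absolute differences in total RNA between arrays do not remain in such values. The intensity medians of the deposited arrays ran from 299 (siMAP4K4 replicate 3) to 321 (siMAP4K4 replicate 2), so the 6 distributions were close but not identical. The plan had assumed values already on a log2 scale. Because the deposited values were linear, log2 was taken first, as the plan provided for, and no further normalization was applied. The settings of RMA and any filtering before deposition are not given in the sources used here, and how much background remained in the value of a dim probe set was not measured.

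Gene names came from a probe annotation table, which lists 18764 of the probe sets, 18331 of them with 1 gene symbol and 433 with several, and leaves 7163 unnamed. Probe sets with several symbols or none were not used for genes. Of the Entrez identifiers of the genes, 17939 were found in a RefSeq gene table of the assembly GRCh38.p14, 26 were not, and 0 symbols were changed. For the 299 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays was used. XIST and genes on the Y chromosome, 23 in all, were left out. No filter on dim probe sets was set, and 17965 genes were tested.

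Differences between siMAP4K4 and scrambled arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, not robust, two-sided), with Benjamini-Hochberg adjustment over all 17965 genes and a threshold of 0.05 on the adjusted p. Log2 fold changes are siMAP4K4 minus scrambled. The fit with the group alone is called the unpaired fit. A second fit, set beforehand with it, added the replicate number as a block and is called the paired fit. The replicate numbers were taken to pair the arrays because the series description ties the replicates to 3 occasions of cell preparation and because the deviations of same-numbered arrays from their group means correlated across genes, at r = 0.23, 0.19 and 0.50 for replicates 1, 2 and 3. Scrambled replicate 1 correlated about as closely with siMAP4K4 replicate 2 (r = 0.25). Genes are not independent replicates, so these correlations carry no p-value. The number of arrays, 3 per group, limits the precision: the median standard error of a log2 fold change was 0.09 in the unpaired fit and 0.08 in the paired fit. The smallest two-sided exact permutation p that 3 arrays against 3 can give is 0.1.

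Both fits were tested on simulated data of the comparison of siMAP4K4 with scrambled arrays, with 17965 genes of which 200 were changed 1.5-fold or 2-fold. A further list of genes was shifted by a smaller amount and was not counted among the unchanged genes. The values were drawn from the paired model with independent noise for each gene. The better recovery of the paired fit was therefore built in and does not bear on whether the pairing holds. The unpaired fit recovered 72% of genes changed 1.5-fold and 99% of genes changed 2-fold, and 0 of its 171 calls were unchanged genes. The paired fit recovered 100% at both sizes, and 18 of its 236 calls (7.63%) were unchanged genes.

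A set of 26 gene lists, with 682 members of which 635 were measured, was fixed before the data were examined, together with both fits, the naming rule and most of the alternatives. They cover the MAP4K family; endothelial identity, lymphatic endothelium, junctions, tip cells and the flow response; Notch, NF-kB, interferon, TGF-beta and BMP, YAP/TAZ and immediate early genes; integrins, matrix and matrix proteolysis; S phase, G2/M and p53 targets; sterol synthesis, hypoxia and glycolysis, the ATF4 and unfolded protein response, and autophagy and lysosome; and markers of smooth muscle, pericytes and fibroblasts, of leukocytes and erythroid cells, and of epithelium. The result of 1 further list, which was tested with the others and counts among the 26, is not reported here. In these lists 30 genes stand in more than 1. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 26 lists, with camera at a correlation estimated per list and with fry as alternatives. Members past the threshold were counted over all genes tested and also adjusted over the list alone.

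The genes named are MAP4K4, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, and for each list up to 4 members past the threshold with the largest change or, where none passed, the 2 with the smallest p, with unnamed loci skipped. The same rule was applied to the paired fit after the data had been examined. Other alternatives were the 40% dimmest genes left out, quantile normalization, median centring, the mean of all probe sets of a gene, every probe set by itself, trend and robust estimation, array weights, and each array left out. Variations of the paired fit, each replicate pair left out included, were added after the data had been examined. Probe sets of near-identical genes, such as those for histones, can bind transcripts of related genes, and their values are uncertain for that reason.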

Results

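Gene expression was profiled on arrays in serum-starved HUVECs, primary endothelial cells of the human umbilical vein, 48 hours after transfection with a scrambled siRNA (3 arrays) or an siRNA against MAP4K4 (3 arrays). Levels are log2 of the deposited RMA intensities. The mean correlation of an array with the other 5 across probe sets was lowest for scrambled replicate 3 (r = 0.989) and highest for siMAP4K4 replicate 1 (r = 0.994). The comparison asked which transcripts change in starved endothelial cells when MAP4K4, a kinase of the Ste20 group, is depleted.

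MAP4K4 transcripts were strongly reduced by the siRNA. The MAP4K4 probe set (Entrez gene 9448) had a log2 level of 11.41 ± 0.06 in scrambled cells and 9.66 ± 0.19 in siMAP4K4 cells (SD, n = 3 each), with single arrays at 11.35, 11.46 and 11.44 against 9.79, 9.45 and 9.75. The log2 fold change was -1.75 (SE 0.10, limma adjusted p = 0.000124), so that 29.7% of the scrambled level remained (95% confidence interval 25.3 to 34.8%). MAP4K4 had the largest fall and the smallest p of the 17965 genes tested. The exact permutation p was 0.1, the smallest that 3 arrays against 3 can give. The 5 measured relatives of MAP4K4 did not pass the threshold over all genes in either fit (adjusted over the list alone, 0 unpaired and 1 higher paired), with TNIK at a log2 fold change of 0.30 (adjusted p = 0.354, paired 0.0757) and NRK at 0.20 (adjusted p = 0.888), and the list as a whole was not called (camera adjusted p = 0.188).

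Changes are ranked here among the genes past the threshold of the fit named. Log2 fold changes are the same in both fits, which differ in their standard errors. Beyond the target, DOK5, RGS2 and TMEM156 had the largest rises and ESCO2, CALU and H3C2 the largest falls in the unpaired fit. In that fit 58 genes passed the threshold, 13 higher and 45 lower after MAP4K4 knockdown, and 50 of them differed at least 1.5-fold (12 higher, 38 lower). With the replicate number as a block, 475 genes passed, 191 higher and 284 lower, 153 of them at least 1.5-fold (46 higher, 107 lower), and all 58 genes were among the 475. At an unadjusted p under 0.05 the unpaired fit had 1448 genes, 712 higher and 736 lower, and the paired fit 2202, 1155 higher and 1047 lower. The 2 groups did not overlap for 2100 genes, or 11.7% of those tested, where chance gives 10%. The unpaired count rested on single arrays: without siMAP4K4 replicate 2 it was 1, without siMAP4K4 replicates 1 or 3 it was 18 or 16, and without scrambled replicates 1 or 3 it was 98 or 89. The balance of calls also moved: without scrambled replicate 3, 40 genes were higher and 49 lower. The paired count lay between 409 and 501 when any replicate pair was left out. With so few arrays left, such a fit leans on the variance pooled over genes, and which genes these counts shared was not examined. Median centring of the arrays took the unpaired count to 2 and the paired count to 429. When every one of 25903 probe sets was tested by itself with pairing, 115 passed.

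Among genes past the threshold in the unpaired fit, DOK5, an adaptor of receptor tyrosine kinases, rose the most. Its log2 fold change was 1.00 (SE 0.09, adjusted p = 0.00332). RGS2, which shortens signalling by G proteins, rose by 0.98 (SE 0.16, adjusted p = 0.0424), and TMEM156 rose by 0.85 (SE 0.14). The glucose transporter gene SLC2A3 rose by 0.72 (SE 0.11, adjusted p = 0.0301), and PLA2G4A, which encodes the cytosolic phospholipase that releases arachidonic acid, rose by 0.69 (SE 0.09, adjusted p = 0.0194). Rises between 0.59 and 0.76 were measured for DOCK10, NAV3, SPOCD1, KHDRBS3, NCR3LG1 and NRIP3, and for IL1RL1, the receptor of interleukin 33. PTGS1, the constitutive cyclooxygenase, had a larger log2 fold change of 1.17 but did not pass in the unpaired fit (adjusted p = 0.0651). It had the largest rise among genes past the threshold with pairing (paired SE 0.11, adjusted p = 0.000492). MGARP (0.95), ERRFI1 (0.81), an inhibitor of the EGF receptor, HTR2B (0.80), a serotonin receptor, and IL7R (0.72) also rose in the paired fit (adjusted p = 0.00212, 0.00111, 0.00144 and 0.0195) and did not pass unpaired, with adjusted p of 0.153, 0.0804, 0.0804 and 0.0901.

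After MAP4K4, the largest falls among genes past the threshold in the unpaired fit were those of ESCO2 and CALU. ESCO2, which acetylates cohesin during replication, had a log2 fold change of -1.25 (SE 0.20, adjusted p = 0.0381). CALU, a calcium-binding protein of the secretory pathway, was at -1.23 (SE 0.17, adjusted p = 0.0238). IFIT1 (-1.30) and IFITM1 (-1.26) were lower still but did not pass unpaired. The histone genes H3C2 and H2BC14 fell by 1.18 and 1.12 on the log2 scale, with the limit that histone probe sets can bind related transcripts. TOP2A, MKI67 and BUB1, genes of dividing cells, fell by 1.14, 1.05 and 1.01. PSMD10 (-1.07), a chaperone of the proteasome cap, TMEM263 (-1.05), LIN7C (-0.94) and SKAP2 (-0.93), an adaptor of Src family signalling, completed the 12 largest falls of genes past the threshold, with standard errors between 0.11 and 0.18. The plot of the largest changes shows each array of these genes.

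**Figure D1:**
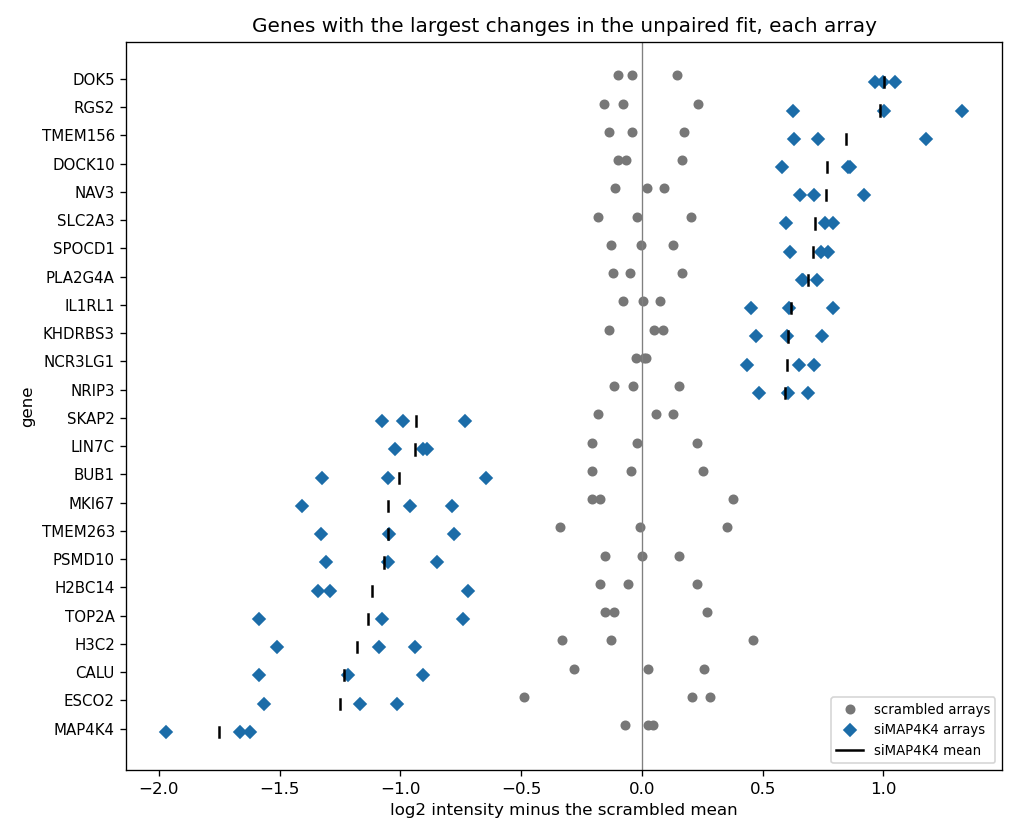
Log2 intensity of each array minus the mean of the scrambled arrays (horizontal axis) for the 12 largest rises and 12 largest falls among genes past the threshold in the unpaired fit (vertical axis), with grey circles for the 3 scrambled arrays, blue diamonds for the 3 siMAP4K4 arrays and a black bar for the siMAP4K4 mean. The groups do not overlap for any of these genes, which the naming rule required, and MAP4K4 lies lowest with a mean of -1.75.

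Genes of mitosis were lower as a group after MAP4K4 knockdown. All 29 measured members of the G2/M list had values below 0, with a median log2 fold change of -0.76 and medians of -0.45, -0.89 and -0.83 in the pairs of replicates 1, 2 and 3. In the unpaired fit 6 of the 29 fell and 23 did not pass, among them the spindle checkpoint genes BUB1 (-1.01, SE 0.17) and BUB1B (-0.78, SE 0.12), which fell. In the paired fit 26 fell, and CDK1, the kinase that drives entry into mitosis, fell by 1.17 (paired SE 0.20, adjusted p = 0.0095) and ANLN, a scaffold of the cytokinetic ring, by 1.11 (paired SE 0.11, adjusted p = 0.000825). Adjusted over the list alone, 28 of the 29 fell in either fit. The camera test called the list lower (adjusted p = 2e-46) at the preset correlation of 0.01, whereas the estimated correlation was 0.60 (paired 0.36). The call was lost with the estimated correlation (adjusted p = 0.223, paired 0.438).

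Genes of DNA replication were lower by a smaller amount. Of the 25 S phase genes, 24 had values below 0, with a median of -0.21 and pair medians of -0.19, -0.23 and -0.36. No member passed in the unpaired fit over all genes, 11 fell when adjusted over the list alone, and 7 fell in the paired fit (12 adjusted over the list alone). CCNE2 (-0.60), a cyclin of S phase entry, CDC6 (-0.60), a licensing factor, RRM2 (-0.47), a subunit of ribonucleotide reductase, and MCM4 (-0.45), a subunit of the replicative helicase, were the largest of these 7, with paired adjusted p between 0.0161 and 0.0377. UHRF1 fell by 0.44 in the paired fit by its brighter probe set, whereas its other probe set had a log2 fold change of 0.05. The list was called lower by camera (adjusted p = 4.47e-15), and the call was lost with an estimated correlation (adjusted p = 0.212, paired 0.336).

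Interferon-stimulated genes, which are induced by antiviral signalling, were lower after knockdown but unevenly between pairs. Of 33 measured members 31 had values below 0, with a median of -0.48 and pair medians of -0.53, -0.11 and -0.69. None passed in the unpaired fit over all genes and 12 fell when adjusted over the list alone. In the paired fit 14 fell (25 adjusted over the list alone), led by IFIT1 (-1.30, paired SE 0.17, adjusted p = 0.00226), OAS2 (-1.17, paired SE 0.14, adjusted p = 0.00152), MX1 (-1.11, paired SE 0.12, adjusted p = 0.00111) and IFI44L (-0.95, paired SE 0.10, adjusted p = 0.00108). Outside the list, the interferon-induced gene IFITM1 fell by 1.26 in the paired fit (adjusted p = 0.00504), whereas GBP2, another interferon-induced gene, named here after its value was seen, rose by 0.55 (adjusted p = 0.00498). The scrambled arrays themselves differed: MX1 was at 10.79, 9.94 and 11.20 in scrambled replicates 1, 2 and 3 and at 9.62, 9.25 and 9.75 in the siMAP4K4 replicates. Without the pair of replicate 2, 26 members fell, and without scrambled replicate 3 the unpaired median was -0.27. Camera called the list lower (adjusted p = 8.39e-21), which was lost with an estimated correlation (adjusted p = 0.498, paired 0.64).

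**Figure D2:**
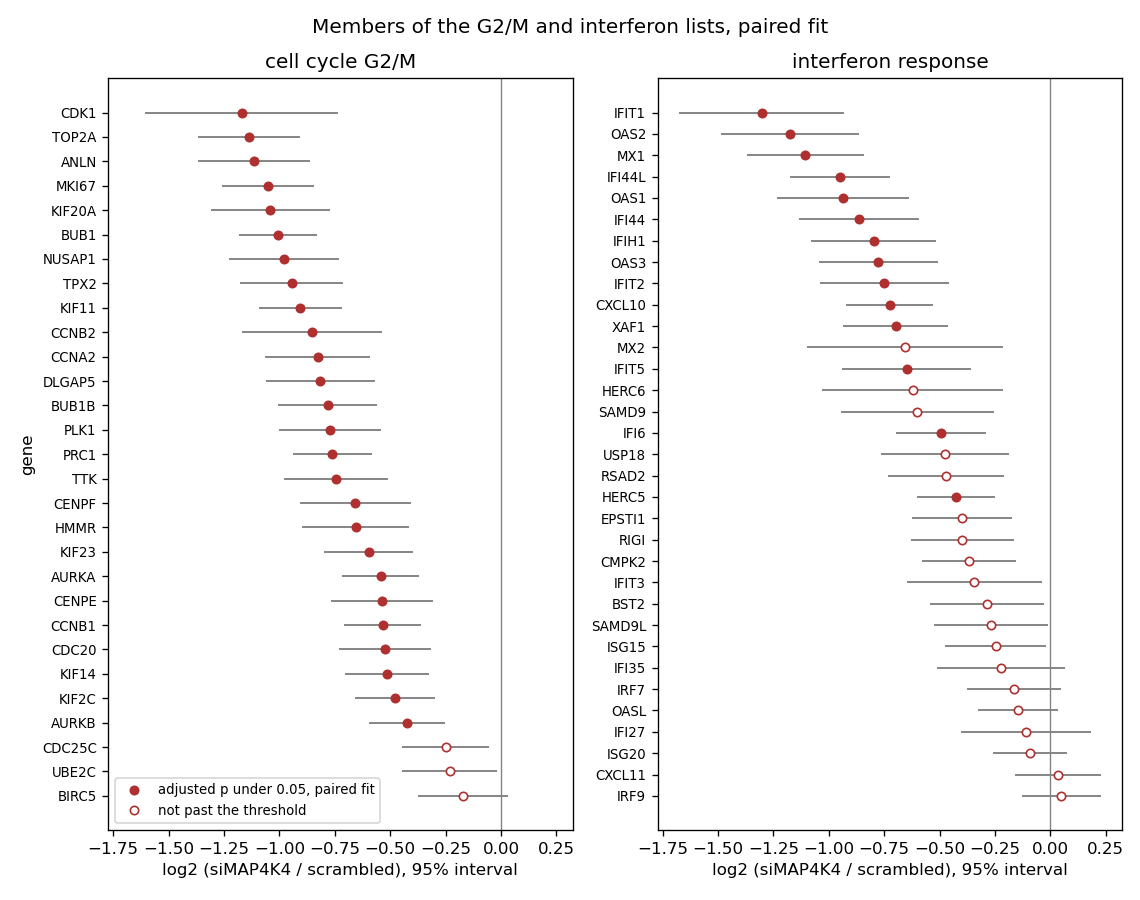
Log2 fold change, siMAP4K4 over scrambled, with its 95% confidence interval from the paired limma fit (horizontal axis), for each measured member of the G2/M and interferon lists (vertical axis). Filled circles passed an adjusted p of 0.05 over all genes and open circles did not: 26 of 29 G2/M genes and 14 of 33 interferon genes are filled, all of them below 0.

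Genes of sterol and fatty acid synthesis had values above 0 in 22 of 24 cases (median 0.18), but this came mainly from the pair of replicate 2, with pair medians of 0.00, 0.41 and 0.10. None passed unpaired or when adjusted over the list alone there. In the paired fit the cholesterol synthesis enzymes DHCR7 (0.49), MSMO1 (0.47) and SC5D (0.37) rose, 7 members rose when adjusted over the list alone, and 0 rose over all genes once the pair of replicate 2 was left out. The camera call (adjusted p = 0.000106, higher) was lost with an estimated correlation (adjusted p = 0.722), and also without scrambled replicate 2 (adjusted p = 0.0701, median 0.09) or siMAP4K4 replicate 3 (adjusted p = 0.084, median 0.10). The median was 0.34 without scrambled replicate 3, 0.34 without siMAP4K4 replicate 1, 0.12 without siMAP4K4 replicate 2 and 0.04 with array weights.

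Single members of the endothelial junction, endothelial identity and tip cell lists fell. CTNNB1, which encodes beta-catenin, fell by 0.76 (SE 0.10, adjusted p = 0.0194), the only one of 20 junction genes to pass unpaired (2 adjusted over the list alone). CTNNA1 (-0.37), alpha-catenin, joined it in the paired fit (adjusted p = 0.0266). CD34, a sialomucin of vascular and stem cells, was at -0.91 (adjusted p = 0.0715) and fell in the paired fit (adjusted p = 0.00344), as the sole member of 29 endothelial identity genes (2 lower when adjusted over the list alone, unpaired). CXCR4, a chemokine receptor of sprouting cells, was at -0.81 (adjusted p = 0.0552) and fell in the paired fit (adjusted p = 0.00462), the only tip cell gene of 23 to do so (1 lower adjusted over the list alone, unpaired). Camera called the junction, identity and tip cell lists lower (adjusted p = 0.0192, 0.00106 and 0.0209), with medians of -0.09, -0.10 and -0.11, and all 3 calls were lost with an estimated correlation (adjusted p = 0.606, 0.53 and 0.606). These calls rested on single arrays: none of the 3 was made without scrambled replicate 3 (camera adjusted p = 0.123, 0.0545 and 0.183) or without siMAP4K4 replicate 2 (0.136, 0.0534 and 0.0912), and that of the tip cell list was also lost without siMAP4K4 replicate 1 (0.0604). Without scrambled replicate 3 the medians were -0.05, -0.05 and -0.05, that of the identity list was -0.05 without siMAP4K4 replicate 2, that of the tip cell list -0.07 without siMAP4K4 replicate 1, and the pair medians of the tip cell list were 0.01, -0.06 and -0.21. With array weights the 3 medians were -0.08, -0.03 and -0.07, and of all lists 4 were called lower, against 6. Of 19 lymphatic genes, SEMA3A (0.72), a guidance ligand, and LYVE1 (0.62), a hyaluronan receptor, rose in the paired fit and, adjusted over the list alone, 2 rose unpaired. That list was not called (camera adjusted p = 0.239), except higher without scrambled replicate 3 (0.0458) or with array weights (0.0168).

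Markers of contractile and stromal cells had slightly positive values in the same arrays. Among 20 markers of smooth muscle, pericytes and fibroblasts (median 0.07), none passed unpaired, 3 rose adjusted over the list alone, and TAGLN (0.64), FAP (0.56), ACTA2 (0.40) and RGS5 (0.39) rose in the paired fit. Of 30 TGF-beta and BMP targets (median 0.05), none passed unpaired, 7 rose adjusted over the list alone, and INHBA (0.66), a subunit of activin, BMP2 (0.38), TAGLN and ACTA2 rose in the paired fit, the last pair of genes being shared by both lists. Camera called both lists higher (adjusted p = 0.0192 and 0.0449), and both calls were lost with an estimated correlation (adjusted p = 0.53 and 0.631). The first was also lost without scrambled replicate 3 (adjusted p = 0.0608, median 0.03) or siMAP4K4 replicate 2 (adjusted p = 0.051, median 0.01), and the other without scrambled replicates 1 or 2 or siMAP4K4 replicates 1 or 3 (adjusted p = 0.125, 0.316, 0.245 and 0.276, medians 0.07, 0.02, 0.08 and 0.03). Without scrambled replicate 3 the median of the TGF-beta and BMP list was 0.09. With array weights it was 0.14, and that of the smooth muscle, pericyte and fibroblast markers was 0.01. No marker of leukocytes and erythroid cells (19 measured) or epithelium (15 measured) passed in either fit, over all genes or adjusted over the list alone, and neither list was called (camera adjusted p = 0.534 and 0.364). CD68 was at 0.29 and MS4A1 at 0.19 in the former, and KRT18 at 0.12 and KRT5 at 0.19 in the latter.

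In the list of p53 targets, 14 of 18 genes had values above 0 (median 0.15), and camera called it higher (adjusted p = 0.0181), which was lost with an estimated correlation (adjusted p = 0.53). The pair medians were 0.04, 0.25 and 0.04, so the shift came mainly from the pair of replicate 2. Without scrambled replicate 2 the call was lost (adjusted p = 0.205, median 0.10), without siMAP4K4 replicate 2 the median was 0.08, and in the paired fit without that pair it was 0.04 (adjusted p = 0.372). Over all genes, its only member to pass was TP53INP1, which fell by 0.52 in the paired fit (adjusted p = 0.0124). Adjusted over the list alone, 0 rose and 1 fell unpaired, and 3 rose and 1 fell paired. Genes of matrix proteolysis were called higher with pairing (camera adjusted p = 0.0459, unpaired 0.0701, and 0.64 for the adjusted p with an estimated correlation). The paired estimated correlation of this list was -0.03, below the preset 0.01, so correlation cannot account for that loss. Among its 24 members the protease inhibitor gene SERPINE2 (0.59), the tissue plasminogen activator gene PLAT (0.51) and the urokinase receptor gene PLAUR (0.33) rose and the membrane protease gene MMP14 (-0.39) fell in the paired fit. Unpaired, 2 rose and 1 fell when adjusted over the list alone. The autophagy and lysosome list (20 genes, median 0.09) was likewise called with pairing (camera adjusted p = 0.0459, unpaired 0.0701), with no member past the threshold in either fit and an adjusted p of 0.743 with an estimated correlation. MCOLN1 was at 0.16 and SQSTM1 at 0.17. Both calls depended on single arrays or pairs. The paired call of the proteolysis list was lost without the pair of replicate 1 or 3 (adjusted p = 0.115 and 0.0892) and that of the lysosome list without the pair of replicate 1 or 2 (adjusted p = 0.225 and 0.156). Unpaired, the proteolysis list was called without siMAP4K4 replicate 2 (adjusted p = 0.0336), and its median of 0.04 was 0.10 without siMAP4K4 replicate 3. The lysosome list was called unpaired without scrambled replicate 3 (adjusted p = 0.000255, median 0.18) and without siMAP4K4 replicates 1 or 2 (adjusted p = 0.0458 and 0.0277), and its median was 0.05 without siMAP4K4 replicate 3.

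The remaining lists reported were not called by camera in either fit. When arrays or a pair were left out or weighted, of these only the NF-kB list (without scrambled replicate 3, siMAP4K4 replicate 1 or the pair of replicate 1, adjusted p = 0.036, 0.0397 and 0.0159) and the YAP/TAZ list (without scrambled replicate 3 or siMAP4K4 replicate 2 or with array weights, adjusted p = 0.00669, 0.0277 and 0.0236) were called, both higher. Of 30 NF-kB genes, none passed unpaired (camera adjusted p = 0.339), while IL1A (0.80), ICAM1 (0.46) and SELE (0.44), a cytokine and 2 adhesion molecules for leukocytes, rose and the chemokine gene CCL5 (-0.38) fell with pairing. Among 31 Notch genes (adjusted p = 0.532) the transcription factor gene HEY2 (0.41) rose and the sheddase gene ADAM17 (-0.37) fell with pairing. PHLDA1 fell by 0.58 (SE 0.09, adjusted p = 0.0311) among 24 immediate early and ERK feedback genes (list adjusted p = 0.739), joined by the feedback inhibitor SPRY1 (-0.56) with pairing. SLC2A3 was the only one of 20 hypoxia and glycolysis genes to pass (list adjusted p = 0.559). Of 40 matrix genes (list adjusted p = 0.658), FBLN5 (0.55) rose and FBN1 (-0.44) fell with pairing. STC2 (0.41) rose and SEL1L (-0.37) fell with pairing among 28 genes of the ATF4 and unfolded protein response (list adjusted p = 0.989). No member of the integrin and focal adhesion (37 genes), YAP/TAZ (22) or flow response (16) lists passed in either fit (list adjusted p = 0.539, 0.364 and 0.8), with ITGA5 at 0.30, AXL at 0.34 and THBD at -0.39 as the members with the smallest p. Adjusted over the list alone and unpaired, the counts in these 9 lists were 1 higher for Notch and for hypoxia, 1 higher and 2 lower for immediate early genes, 1 lower for the flow response and 0 for the others.

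**Figure D3:**
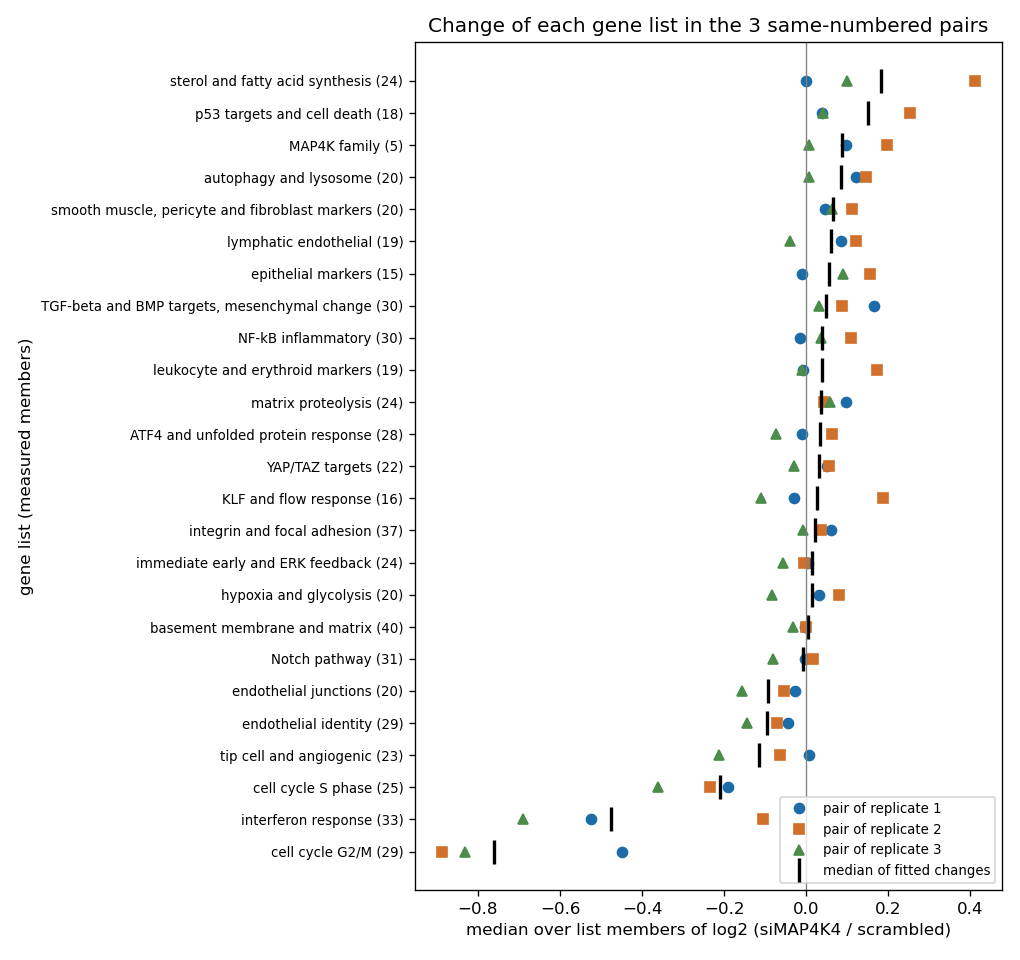
Median over the members of each of 25 gene lists of the log2 difference between siMAP4K4 and scrambled (horizontal axis), with circles, squares and triangles for the same-numbered pairs of replicates 1, 2 and 3, a black bar for the median of the fitted changes, and the number of measured members in parentheses. The G2/M list lies at -0.45, -0.89 and -0.83, the interferon list at -0.53, -0.11 and -0.69, and the sterol list at 0.00, 0.41 and 0.10.

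In all, camera called 10 of 26 lists unpaired (4 higher, 6 lower) and 12 paired (6 higher, 6 lower), whereas with an estimated correlation and with fry the count was 0 in both fits, with lowest adjusted p of 0.212 and 0.151 unpaired. Because the estimated correlation leaves camera few degrees of freedom here, its count of 0 does not show that no list changed. Other divisions of the same 6 arrays into groups of 3 gave up to 15 called lists unpaired.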

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

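The tests of the scrambled siRNA, of siRNA off-targets and of the unnamed probe sets, the range around each share of falls, and the counts without each replicate pair were chosen after the results were seen. The other tests were set before their values were seen.

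A few probe sets outside the gene comparison passed the threshold. When every one of 25903 probe sets was tested by itself with pairing, 115 passed in limma, and 7 of these, 2 higher and 5 lower in siMAP4K4 arrays than in the scrambled controls, were among the 7163 without a gene name. All 7 lay near the threshold, with adjusted p between 0.0354 and 0.0464, and in the paired gene comparison 7.63% of the calls on simulated data were false. Without pairing 0 unnamed probe sets passed. The largest of these changes were probe sets 8116418 (0.76) and 8021635 (0.59), which rose, and 7916584 (-0.63) and 8135069 (-0.62), which fell.

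The lower level of G2/M genes was weighed against array scale and against a single cell preparation. After quantile normalization of the arrays the median log2 fold change of the 29 members was -0.76. The median of the signed shifts of fold changes over all genes was -0.000847, which does not show how far single genes moved. Because RMA had already made the array distributions close, the test could hardly have come out otherwise. It shows that scale differences left in the deposited values did not make the shift, and cannot decide on differences that RMA had removed. The highest of the 3 pair medians was -0.45, so the shift was present in every pair and did not come from a single preparation. It may reflect fewer dividing cells after MAP4K4 knockdown, as a hypothesis found and examined on the same data. No measure of cell number or cycle phase was analysed here, and an off-target effect of the siRNA stays open.

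For the interferon genes, the median was -0.47 after quantile normalization, and the same limit of the array scale test holds. The test of a single cell preparation was left undecided by the criterion set for it, a median below -0.2 in all 3 pairs, since the highest pair median was -0.11 and the other pairs lay at -0.53 and -0.69. Values added afterwards bear against a single preparation as the whole cause. Without the pair of replicate 1, 2 or 3, the list median was -0.48, -0.62 or -0.34, and the paired fit called 15, 26 or 13 members lower. These calls lean on the variance pooled over genes, because few arrays remain. Whether the scrambled siRNA raised these genes and the MAP4K4 siRNA did not cannot be told apart from a loss caused by knockdown, because the series as analysed here has 0 untransfected arrays. MX1 varied from 9.94 to 11.20 among scrambled arrays.

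Among genes that differed at least 1.5-fold, whatever their p, 114 were lower and 47 higher, so falls made up 70.8%. The excess was lost without scrambled replicate 3: over the arrays left out in turn the share ran from 46.8 to 80.8%, lowest without that array. After quantile normalization the share was 70.4%, above the limit of 60% set beforehand, and it ran from 49.7 to 80.9% with arrays left out. That range reflects dependence on single arrays and does not bear on scale. The step left the share nearly as it was, but cannot decide on differences that RMA had removed, so array scale stays open in that respect. Without the members of the S phase, G2/M and interferon lists the share was 62.4% (39.1 to 75.6%), and the part these genes play stays open too. The lists hold only some genes of these kinds: ESCO2 (-1.25) and IFITM1 (-1.26), for example, lie outside them. Leaving out the lists therefore cannot decide what genes of the cell cycle and interferon response contribute. Outside the lists 78 genes were at least 1.5-fold lower, ESCO2 and IFITM1 among them. Off-targets of the siRNA could not be tested because its sequence is not given in the sources used here.

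The 6 arrays can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The real division called 58 genes unpaired, 50 of them at least 1.5-fold, and the highest of the other divisions called 0 in both cases, so 1 of the 10 reached the real count. Every other division mixes siMAP4K4 and scrambled arrays within each group. Any effect of the siRNA then adds to the variation within groups and lowers gene counts, so low counts there do not measure chance. For gene lists the real division called 10 and the highest other 15, and 4 of the 10, the real one included, called at least as many. In the 4 divisions that part all 3 replicate pairs, also too few for a share under 0.05, the paired fit called 475 genes in the real one and at most 0 in the others, and 12 lists against at most 8, so that 1 of the 4 reached each real count. The same mixing of treatments limits the gene counts of these divisions.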

How the results depend on the processing

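The variations of the paired fit and the paired probe set test were chosen after the data were examined, the other alternatives before. MAP4K4 stayed past the threshold under every alternative run, with log2 fold changes between -1.82 and -1.64 for the unpaired alternatives and the replicate block, -1.85 and -1.62 when replicate pairs were left out, and -1.75 with every probe set tested by itself. The count of 58 genes (13 higher, 45 lower) became 475 with the replicate block, 437 with array weights (211 higher, 226 lower), 2 with median centring (MAP4K4 lower and DOK5 higher, so 1 of each direction) and 2 with every probe set tested by itself, and the causes were not tested. It ran from 1 to 98 when each array was left out (1 without siMAP4K4 replicate 2, 18 and 16 without replicates 1 and 3, 98, 46 and 89 without scrambled replicates 1, 2 and 3), where fewer arrays also lower the power. The count of 50 genes at 1.5-fold became 153 with the replicate block, 105 with array weights and 2 with median centring, and ran from 1 to 90 when each array was left out. Quantile normalization gave 68 genes, 47 of them among the 58. The 10 gene lists became 0 with an estimated correlation and 0 with fry, and 7 to 12 under the other alternatives, with 3 lists lower in place of 6 without scrambled replicate 3 or siMAP4K4 replicate 2. With array weights 5 lists were higher and 4 lower, against 4 and 6. With the dimmest 40% of genes left out 3 were higher and 5 lower. Median centring and the mean of all probe sets of a gene each gave 3 higher and 6 lower. The replicate block added the matrix proteolysis and autophagy lists and changed no other list call.

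The paired count of 475 ran from 422 to 540 over filtering, normalization, centring and robust estimation. With every one of 25903 probe sets tested by itself, 115 passed in the paired fit, and the cause was not tested. The count was 501, 409 and 442 without the pair of replicate 1, 2 or 3, in fits that lean on the variance pooled over genes because few arrays remain. The 12 lists of the paired fit were 7 without the pair of replicate 2 and 11 without either other pair. Of the 3 sterol genes called with pairing, 0 were called without the pair of replicate 2. The paired fit called 4 S phase genes without the pair of replicate 3, against 7, and 11 G2/M genes with the dimmest 40% of genes left out, against 26, since not all members were then tested. Over the 104 named genes and the 13 alternatives of the unpaired fit, the replicate block and single arrays left out included, no called gene reversed its direction, 1108 values stayed on their side of the threshold, 116 lost it and 110 gained it. For many values a reversal was excluded in advance. The replicate block and the trend and robust fit keep the fold change. Leaving out an array cannot reverse genes named for the largest changes, whose groups did not overlap. Of the 110 gains, 52 came from the replicate block, and many named genes were chosen because they passed there. With the dimmest 40% left out, 86 of the 104 genes had a value. Signal over background was not given, so what dim probe sets limit was not measured.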

Other observations

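The gene groups here were chosen after the values were seen, and the values are given without an explanation.

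Canonical histone genes, H3C2 and H2BC14 included, mostly had lower values after MAP4K4 knockdown. Of 55 measured, 47 had values below 0, with a median log2 fold change of -0.21 and pair medians of -0.13, -0.10 and -0.37. In the unpaired limma fit 3 fell, H3C2 and H2BC14 among them, and 0 rose, and in the paired fit 10 fell and 1 rose. H1-5, a linker histone, fell by 0.88 (SE 0.11, adjusted p = 0.0133) and H2BC7 fell by 0.93 in the paired fit (adjusted p = 0.0114), whereas H2BC12 rose by 0.48 in the paired fit (adjusted p = 0.0214). Probe sets of histone genes can bind related transcripts, so the values are not independent of each other.

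Most genes of prostanoid synthesis and of the EGF receptor system did not pass the threshold, and neither group was tested as a list. Of 19 measured genes for prostanoid synthesis and receptors, PTGS1 (1.17), PLA2G4A (0.69) and the prostaglandin E2 receptor gene PTGER4 (0.33, adjusted p = 0.0434) rose, PLA2G4C (-0.45, adjusted p = 0.00959) fell and 15 did not pass in the paired fit, PTGS2 (0.14) and PTGIS (0.13) among them. PLA2G4A was the only 1 of the 19 to pass unpaired. Of 13 measured EGF receptor family, ligand and feedback genes, HBEGF (0.64, adjusted p = 0.00495), ERRFI1 (0.81, adjusted p = 0.00111) and EGFR (0.35, adjusted p = 0.0434) rose in the paired fit and 10 did not pass, and 0 passed unpaired. The median over each group was 0.03 and 0.05.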
